A study of Homo sapiens with 18 samples.

How the data were processed

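Captured 5hmC was sequenced from 6 tumor, 6 peripheral and 6 distant normal gastric samples, grouped by the tissue label of each sample. Per the labels' protocols, 5hmC-bearing fragments were enriched by selective chemical labelling before library preparation, so the reads show where 5hmC was captured and not the share of cytosines that carry it. The extraction protocol speaks of brain tissue, while tissue labels, series title and design name gastric tissue, and the latter were followed. The submitters' processing notes name Bowtie 0.12.6, edgeR 3.8.6 and HOMER 4.8.3 and the build hg19 (GRCh37), without saying what each did. How reads were filtered and counted, the number of positions tested, the normalization and the libraries in each fit are not given in the sources used here. In the sample descriptions, all peripheral libraries belong to lane 5 and all others to lane 4. The titles number the samples so that each run of 3 consecutive numbers holds 1 normal, 1 peripheral and 1 tumor sample, and the design speaks of sets of tissues. No label says that such a run comes from 1 donor, and without values per sample no pairing could be used or checked. Nothing states that samples of a group are from separate donors beyond the design's mention of sets of tissues. The p-values therefore speak for these samples alone, and how the spread between samples enters each p is unknown.

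The deposited tables hold, per the file headers, a position, a log2 fold change, a mean level in log2 CPM, a likelihood ratio score and a p-value for each listed position, all computed by the authors. These columns are named as in the output of a likelihood ratio test of edgeR, which is among the tools in the submitters' processing notes, so the authors' values were read as such output. In all 3 tables the p-value that the authors deposited equals the upper tail of a chi-square distribution with 1 degree of freedom at the likelihood ratio score. The largest p in any table was just under 0.01, the threshold read from the values. No adjusted p is in the tables, and no column holds values per sample, so no model was fitted here, no replicate could be left out and the depth behind a value is unknown. Positions have an end 1 above the start, and the closest neighbours are 2 apart. Coordinates are printed as the starts given by the files, which do not say whether they count from 0 or 1.

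The sign of the fold change is not explained in the headers. It was read from positions listed for both tumor and peripheral tissue. Where both fold changes are negative, their sizes followed each other across 571 positions (Spearman's rho 0.993), as when the reads are those of normal libraries that both comparisons share. Where both are positive there was no such relation across 81 positions (rho -0.05, permutation p = 0.669). Negative was therefore read as lower than normal. The rho serves this reading alone: it comes from the shared normal reads and is no measure of how alike tumor and peripheral tissue are. Positions are not independent replicates. On simulated tables of tumor and peripheral tissue against shared normal tissue, this reading recovered the direction in 2 of 2 cases. That outcome was fixed by how the tables were made. The same normal reads set both fold changes, and tumor and peripheral reads were drawn independently. The simulation is therefore no support for the direction. Reads that vary together in both tissues, which could mislead the rule, were not covered. The coefficient of the 3-group table was read by the sign it shares with the other tables.

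Computation used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Positions were counted per direction, with exact (Clopper-Pearson) 95% intervals that cover counting error only. Positions of the same direction within 1 kb were merged into regions. Positions with an absolute log2 fold change of 5 or more were treated as having reads in 1 group alone, since they follow a curve on which fold is a function of mean level, and none lay between 4.5 and 5. Shared positions have identical coordinates, and random placement was drawn by 100 shuffles within chromosomes. The number of tests that would allow any adjusted p of 0.05 was computed from the listed p-values by the Benjamini-Hochberg rule. The share of higher positions per autosome, on arms and in windows was tested with two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over the 22 autosomes and over 6 arm tests. On simulated tables of peripheral against normal tissue the test found a planted chromosome in 20 of 20 cases and made 0 of 440 false calls. The simulated directions were drawn independently for each position, so false calls from clustered neighbours are not covered. Centromere gaps are those of hg19, written down from memory as no copy was supplied; 0 listed positions lie inside any of the 24. Windows were 1 Mb beside the gaps and 5 Mb at the ends, both chosen after the data were seen. Each flank was measured outward from the listed position nearest the gap on that side, which can lie away from the gap itself.

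The rule for named items, the tests per comparison and part of the alternatives were fixed before the data were examined. The tests of centromere flanks and chromosome ends with all their alternatives, and the other alternatives named as such in the closing section, were added afterwards. The naming rule takes genes where annotation of the same build is at hand, and otherwise takes the 10 positions with the smallest p per direction. The gene table used here is on GRCh38, and on 16 of 24 chromosomes listed positions lie beyond its last gene. It was therefore not used for coordinates, and genomic context and the 21 gene lists fixed in advance were not analysed. Regions named for their number of positions were chosen after the values were seen. The design assumed values per sample as a possibility, and its fallback for the authors' statistics alone was followed. With arms as the unit, the share of higher positions was compared by exact permutation of the arms with 20 or more positions. With autosomes as the unit, an exact sign test was run over autosomes with at least 5 positions expected inside the windows in either direction. Alternatives were stricter p, an absolute log2 fold change of 1 or more, autosomes alone, merged regions, other overlaps and other windows.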

Results

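Gastric tissue was profiled for 5-hydroxymethylcytosine (5hmC), an oxidised form of DNA methylation, by chemical labelling and capture of 5hmC-bearing DNA followed by sequencing. The labels describe 18 samples in 3 groups of 6: gastric tumor, tissue adjacent to the tumor (peripheral) and distant normal gastric tissue. The values analysed here are 3 tables of the authors' own comparisons, for tumor against normal, for peripheral against normal and for all 3 groups. Each lists only genomic positions with an unadjusted p under 0.01. Positions above that threshold are not in them, positions without a true difference can be listed by chance, and no value belongs to a single sample. The depth of the libraries is unknown, and fold changes carry no standard error. In the tables together, 32158 positions were listed. Coordinates are those of the files, on hg19 per the submitters' processing notes. For tumor and for peripheral tissue, lower and higher are relative to normal tissue, a direction read from the positions that the tables share. In the 3-group table they are the sign of a coefficient whose contrast is not named.

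The comparison of tumor with distant normal tissue asks where 5hmC differs in the cancer. Lower 5hmC in tumor made up 14281 of the 14593 listed positions (97.9%, exact 95% binomial interval 97.6 to 98.1), and higher 5hmC made up 312. The regions with the most lower positions lay on the long arm of chromosome 1, with 26 between 228774345 and 228779041, 21 between 228744549 and 228747752, 19 between 228758969 and 228763297 and 17 between 228764566 and 228767776. All of these are parts of 1 cluster of 115 lower positions from 228744549 to 228782124 and are not separate loci. Whether that cluster is a repeat collapsed onto the reference stayed open (closing section). A region of 16 lower positions lay on chromosome 18 between 55922988 and 55923410, 1 of 13 on chromosome 19 between 3630230 and 3632896 and 1 of 12 on chromosome 10 between 134238768 and 134239067. By 1 Mb window, lower positions were most frequent on chromosome 19 between 1 and 2 Mb (148 positions), on chromosome 1 between 228 and 229 Mb (136) and on chromosome 16 between 1 and 2 Mb (131). No region of higher 5hmC held more than 3 positions. The regions of 3 were on chromosome 9 from 131924332 to 131924343 and on chromosome 17 from 73893270 to 73893290.

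The smallest p for lower 5hmC in tumor belonged to chromosome 2 at 90481231 in the authors' deposited table (log2 fold change -6.70, p = 2.36e-05). The other 9 of the 10 lower positions with the smallest p lay at 80195845 and 80195854 on chromosome 17, 1039640 on chromosome 7, 1079535 and 1079538 on chromosome 11, 51989892 and 51989896 on chromosome 3, and 45573446 and 45573450 on chromosome 19. These 10 positions formed 6 loci, 5 of the positions lay within 5 Mb of a chromosome end, and all 10 were also listed in the 3-group table. Across these 10 the p rose as the mean level fell, so their ranking by p followed the level. For higher 5hmC in tumor, the authors' deposited table gave the smallest p to chromosome 1 at 228338986 (log2 fold change 6.07, p = 0.000553). It was followed by 39716939 on chromosome 4, 33579849 on chromosome 10 and 157446317 on chromosome 6. Of the 10 higher positions with the smallest p, 4 were also listed as higher in peripheral tissue, at 18930894 on chromosome 16, 36195433 on chromosome 21, 54833987 on chromosome 2 and 62610435 on chromosome 11.

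Levels at nearly all of these tumor positions were low and had the form of reads in 1 group alone. For 14253 lower positions (99.8%) and all 312 higher ones, the fold change was a fixed function of the mean level, as it is where 1 group has no reads. Their fitted fold changes then depend on a constant added by the fit and are neither a measured fold nor a bound on one. The median mean level of the lower positions was 0.515 CPM (counts scaled to library size) in the authors' deposited table. The 28 lower positions off this curve had a median log2 fold change of -3.49 in the authors' deposited table, with a range from -3.67 to -3.20. The highest mean level among the tumor positions, 1.29 CPM, was at 1282058 on chromosome 10 (log2 fold change -3.29, p = 0.00368 in the authors' deposited table). The number of positions tested is not given in the sources used here. None of the listed positions could pass a Benjamini-Hochberg adjusted p of 0.05 if more than 72965 had been tested.

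**Figure D1:**
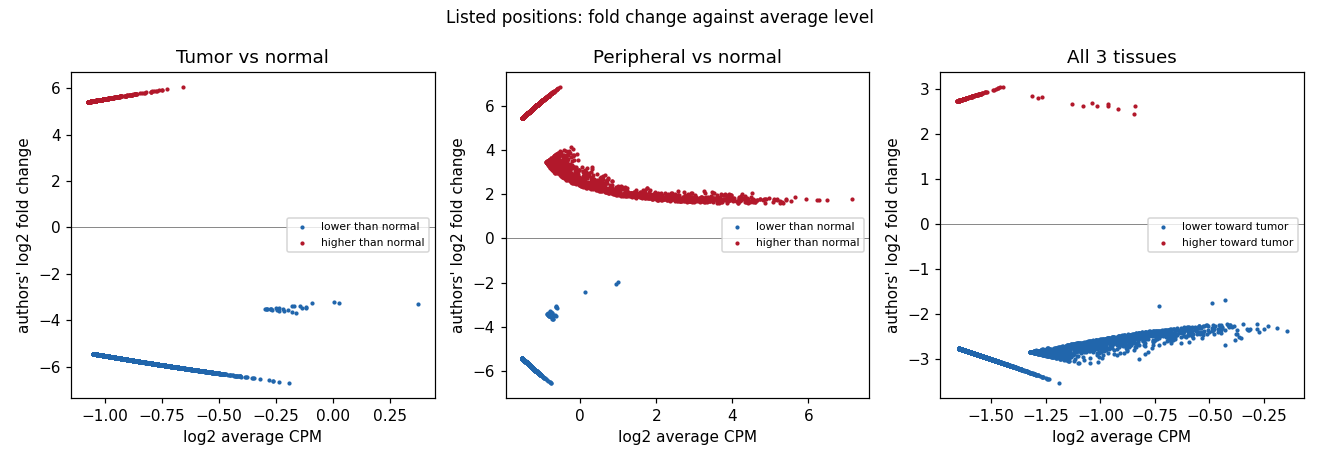
Log2 fold change (vertical axis) against mean level in log2 CPM (horizontal axis) for every position of the 3 tables, each point 1 position. Positions beyond an absolute log2 fold change of 5 fall on narrow curves, and in peripheral against normal 1283 higher positions lie off the curve and reach 143 CPM.

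The comparison of peripheral with distant normal tissue asks whether tissue next to the tumor already differs. Here the direction was the opposite one: 11759 of 15905 listed positions were higher in peripheral tissue (73.9%, exact 95% binomial interval 73.2 to 74.6) and 4146 were lower. Of these, 10476 higher (89.1%) and 4118 lower positions (99.3%) had the form of reads in 1 group alone. Their median mean levels were 0.373 and 0.367 CPM in the authors' deposited table, and their fold changes are neither a measured fold nor a bound on one. Lane coincides with tissue and depth is unknown, so neither can be told apart from a tissue difference in this direction. Higher 5hmC was densest beside the centromeres. On chromosome 10, 1 region between 42383301 and 42399363 held 223 higher positions and another between 42596861 and 42600348 held 79. Chromosome 16 had 78 between 46397464 and 46410411 and 61 between 46386052 and 46395853. Further such regions lay on chromosome 19 between 27732032 and 27740184 (54 positions), on chromosome 2 between 92308968 and 92319477 (44) and on chromosome 17 between 22245803 and 22256537 (38). In the 1 Mb windows with the most higher positions, chromosome 10 from 42 to 43 Mb had 385 and chromosome 16 from 46 to 47 Mb had 248, where the tumor table listed 0 and 1.

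Centromere flanks were the 1 Mb outward from the listed position nearest the gap on each side, 1.45% of the autosomal length compared. The flanks were thus placed by the same positions that were tested. They held 1346 of 11457 higher positions (11.7%) and 43 of 4126 lower ones (1.04%; odds ratio 12.6, two-sided Fisher's exact test, p = 4.29e-131). Adjacent positions share DNA fragments, so this p is too small. After positions within 1 kb were merged, 245 of 7780 higher regions and 31 of 3050 lower regions lay there (odds ratio 3.17, Fisher's exact p = 9.18e-12). With autosomes as the unit, the share in the flanks was larger among higher positions on 11 of the 12 autosomes with enough positions (exact sign test, p = 0.00635). In the tumor table the same flanks held 1 of 310 higher positions and 112 of 14186 lower ones (odds ratio 0.407, Fisher's exact p = 0.737). For all listed peripheral positions the odds ratio was 27.8 with flanks of 0.5 Mb and 6.51 with flanks of 2 Mb. With p under 0.0001, where 143 higher and 11 lower autosomal positions are left, it was 5.38 with flanks of 1 Mb (Fisher's exact p = 0.102). At that threshold flanks of 2 Mb held 39.2% of the higher and 45.5% of the lower positions (odds ratio 0.772, Fisher's exact p = 0.754), and flanks of 0.5 Mb held 30.1% and 0% (Fisher's exact p = 0.0350). The lower ones in the 2 Mb flanks include 4 neighbouring positions on chromosome 18, from 13262330 to 13262360, which are not independent. All peripheral libraries were run on lane 5 and all tumor and normal libraries on lane 4, so lane and tissue cannot be told apart.

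The centromere flanks also held most of the higher positions with reads in both groups. Of these, 952 of 1213 on the autosomes lay in the flanks (78.5%), against 394 of 10244 higher positions on the curve (3.85%). The 1283 higher positions with reads in both groups, on all chromosomes, had a median log2 fold change of 2.40 in the authors' deposited table, and their middle 50% ran from 1.88 to 3.22. The highest mean level was at 121485205 on chromosome 1, where the authors' deposited table gave 143 CPM and a 3.47-fold higher level in peripheral tissue (p = 0.00155). At 27738487 on chromosome 19 the authors' deposited table gave 42.9 CPM and a 3.34-fold higher level (p = 0.00303).

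The smallest p for higher 5hmC in peripheral tissue was at 61723014 on chromosome X in the authors' deposited table (log2 fold change 6.88, p = 1.29e-06). Next came 92290771 and 132997350 on chromosome 2, 46389231 and 34189002 on chromosome 16, 42381488 and 42542798 on chromosome 10, 43829245 and 43823789 on chromosome 8, and 68417247 on chromosome 9. Of these 10 positions, 7 lay in the 1 Mb flanks of the centromeres. For lower 5hmC in peripheral tissue, the authors' deposited table gave the smallest p to chromosome 18 at 13262344 (log2 fold change -6.56, p = 1.41e-05), with 13262330, 13262334 and 13262360 beside it. The others of the 10 were 3097021 and 10708045 on chromosome 1, 77982883 on chromosome 17, 1019378 on chromosome 4, 86006211 on chromosome 16 and 66045220 on chromosome 11. None of these 10 lower positions was listed in another table. Chromosome 19 held the lower regions with the most positions, 17 positions between 36788064 and 36791963 and 14 between 36761845 and 36762869. At most 132146 tests would allow any listed position to pass an adjusted p of 0.05, and 30 would pass at that number.

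The 3-group table gives 1 coefficient and 1 degree of freedom per position, and its contrast is not named in the sources used here. Lower values made up 4406 of its 4553 positions (96.8%, exact 95% binomial interval 96.2 to 97.3) and higher values 147. It shared 1901 lower and 20 higher positions with the tumor table and 891 lower positions with the peripheral table, and 2312 of its positions (50.8%) were in neither. None of the 11759 positions that were higher in peripheral tissue was in it. With the contrast not named, it is unknown whether the coefficient could list such positions at all. Their absence is therefore no evidence about them. The smallest p was at 29446070 on chromosome 22, where the authors' deposited table gave a log2 coefficient of -3.54 (p = 1.09e-04). At this position the authors' deposited tables also gave log2 fold changes of -6.06 in tumor and -6.12 in peripheral tissue. The 10 positions with the smallest p were all lower and all listed in both other tables, among them 1574645 and 1816419 on chromosome 19, 24324743 on chromosome 2 and 11005873 on chromosome 1. The regions with the most positions held 9 between 54315820 and 54315999 on chromosome 16 and 8 between 71511514 and 71512596 on chromosome 1. No listed position of this table could pass an adjusted p of 0.05 with more than 22772 tests.

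Tumor and peripheral tissue shared 652 listed positions. Lower in both were 571 positions, out of 14281 lower in tumor and 4146 lower in peripheral tissue (13.8% of the latter), and all 571 were in the 3-group table too. Higher in both were 81 positions, 26.0% of those higher in tumor and 0.689% of those higher in peripheral tissue. In 100 random placements within chromosomes the mean number shared was 0.02 for lower and 0 for higher positions. Such placement ignores where CpG sites and reads lie, so means near 0 were bound to result and are no measure of chance. The sources used here do not list the normal libraries of each comparison. They were read from the values as shared, the reading on which the direction of every result rests. Part of the overlap may then come from them, and with no values per library this could not be simulated. Opposite directions could hardly occur at shared positions, since normal tissue either has reads at a position or has none. Chosen by the smallest product of p after the values were seen, the shared lower positions began with 29446070 on chromosome 22 and 1574645 on chromosome 19. Chosen in the same way, the shared higher positions began with 61723014 on chromosome X, 54833987 on chromosome 2 and 2590055 on chromosome 16.

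Among the autosomes, lower positions in tumor were densest on chromosome 19 (25.8 per Mb) and sparsest on chromosome 3 (2.52 per Mb). Lower positions were also densest on chromosome 19 in peripheral tissue (7.91 per Mb) and in the 3-group table (6.87 per Mb). Density is per length alone, and where CpG sites and reads lie was not taken into account. The share of higher positions in tumor, each autosome against the others, differed on 3 of 22 autosomes (two-sided Fisher's exact test, Benjamini-Hochberg over 22). It was 4.82% on chromosome 15 (adjusted p = 0.00543), 0.893% on chromosome 19 (adjusted p = 0.00389) and 0.347% on chromosome 22 (adjusted p = 0.00543). In peripheral tissue 15 autosomes differed, 8 with more and 7 with fewer higher positions, and 12 differed after merging. The share there ran from 88.8% on chromosome 8 to 50.3% on chromosome 19. With p under 0.0001 the call was for another autosome, chromosome 18, with 2 higher and 4 lower positions (adjusted p = 0.00448), the lower ones being those from 13262330 to 13262360. These tests count positions as independent, which neighbouring ones are not. In the 3-group table no autosome differed by this test, and none had an unadjusted p under 0.05.

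Listed positions gathered toward the chromosome ends in each table, the lower ones more than the higher ones. The gathering is measured against length alone. Where CpG sites and reads lie was not taken into account, so it cannot be read as a trait of the 5hmC differences. The normal libraries were read as shared, so the 3 tables do not repeat one another independently, and neighbouring positions are not independent either. The outer 5 Mb, 7.25% of the autosomal length, held 36.8% of the lower and 18.4% of the higher positions in tumor (odds ratio for higher 0.387, Fisher's exact p = 3.59e-12; merged 0.411, p = 9.60e-10). In peripheral tissue they held 35.6% of the lower and 12.5% of the higher positions (odds ratio 0.259; merged 0.280, exact p = 2.70e-138). With p under 0.0001 the odds ratio in peripheral tissue was 0.132 for the outer 5 Mb (Fisher's exact p = 0.00995), 0.190 for 10 Mb (p = 0.0259) and 0.438 for 2 Mb (p = 0.411). In the 3-group table the shares were 35.4% and 17.1% (odds ratio 0.377, exact p = 2.17e-06; merged 0.421, p = 5.29e-05).

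Chromosome arms often gained or lost in gastric cancer, taken in advance, were set against all other arms. On the 5 gained arms 98.4% of the tumor positions were lower, against 97.8% elsewhere (odds ratio for higher 0.704, adjusted p = 0.243 over 6 tests). On the 7 lost arms 98.1% were lower (odds ratio 0.864, adjusted p = 0.631). In peripheral tissue 77.9% of the positions on the lost arms were higher, against 72.9% elsewhere (odds ratio 1.32, adjusted p = 8.86e-06). This call was lost with arms as the unit, where the mean share was 78.1% ± 8.24 (SD, 7 arms) against 72.4% ± 11.01 (SD, 32 arms; exact permutation test, adjusted p = 0.413). After merging it held (odds ratio 1.27, adjusted p = 0.00178). At p under 0.0001 all 21 positions on the lost arms were higher, against 91.7% elsewhere (adjusted p = 0.612). Single arms ranged from 48.8% to 89.8%, and 17p, a lost arm, had 64.3%. For the gained arms of peripheral tissue the odds ratio was 0.957 (adjusted p = 0.631). In the 3-group table the gained arms had an odds ratio of 1.64 (adjusted p = 0.116) and the lost arms 1.11 (adjusted p = 0.689).

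**Figure D2:**
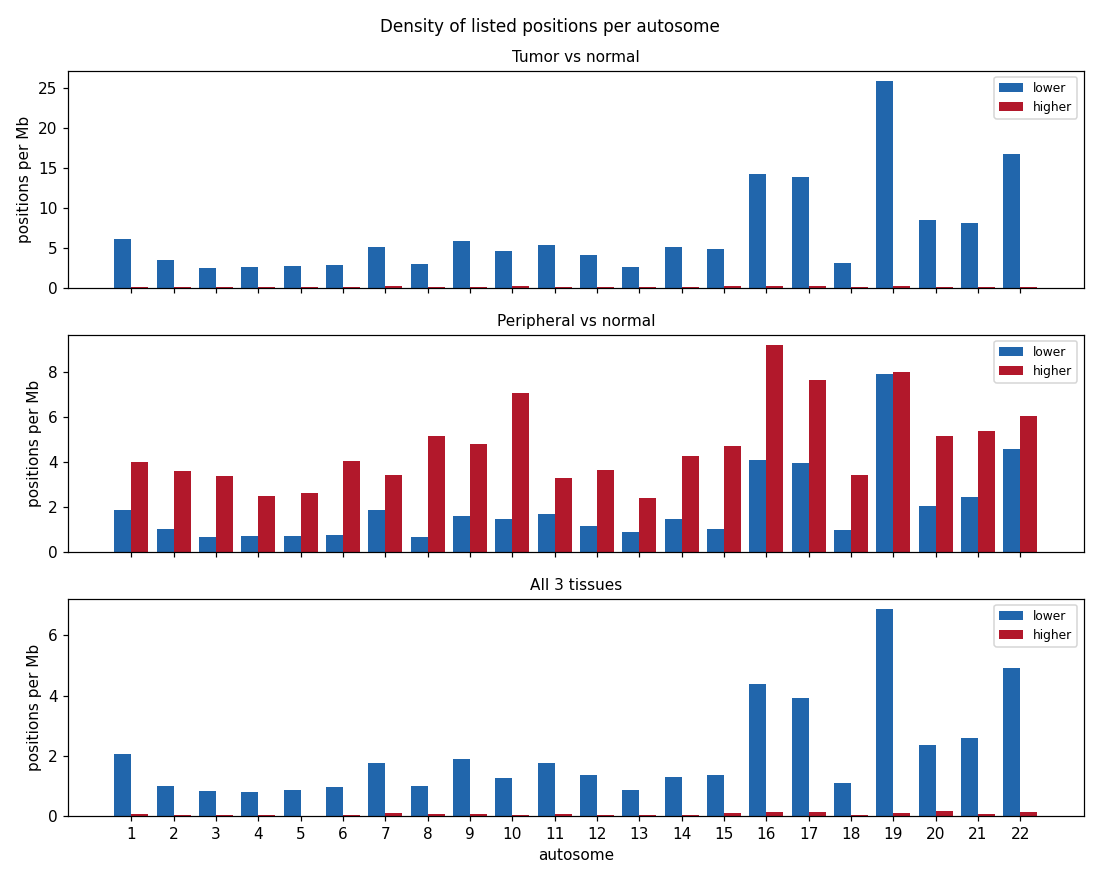
Listed positions per Mb on each autosome (bars from 0), lower and higher separately, for the 3 tables. Per Mb, chromosome 19 has the most lower positions in tumor, 25.8, and chromosome 16 the most higher positions in peripheral tissue, 9.20. On chromosome 16, 248 higher positions lie between 46 and 47 Mb, beside the centromere. After merging within 1 kb, chromosome 16 has 4.59 higher regions per Mb and chromosome 17 has 5.41.

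**Figure D3:**
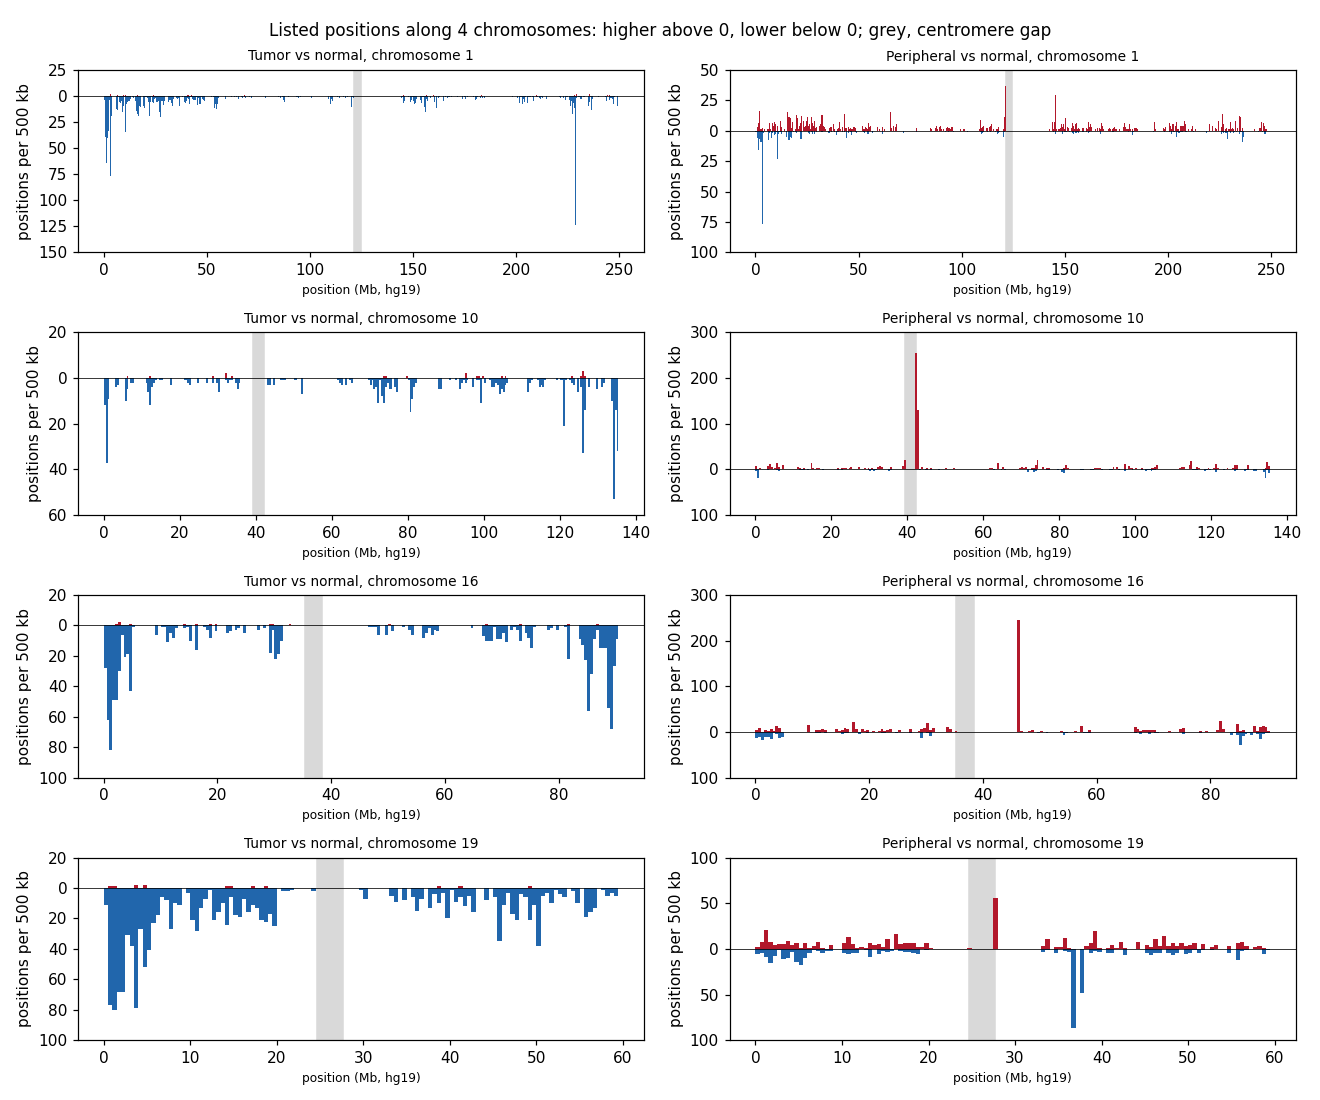
Listed positions in 500 kb bins along chromosomes 1, 10, 16 and 19 (horizontal axis in Mb), tumor against normal on the left and peripheral against normal on the right, with higher positions drawn above 0, lower ones below 0 and the centromere gap in grey. The peaks of higher positions beside the gaps appear in the peripheral panels, as on chromosome 10 from 42 to 43 Mb with 385 positions.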

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

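Of 94 alternatives computed, 13 remove or change nothing by construction (the log2 fold of 1 or more, and the overlap definitions at single positions). Of the others, 49 kept direction and threshold or stayed within 1.5 times a count or inside an interval, 27 moved a value, 3 lost a call and 2 changed direction. Alternatives chosen after the data were seen are all those of the centromere flanks and chromosome ends (windows, merging, p under 0.0001 alone or with other windows, autosomes as the unit), the flanks left out, the fold under 5, the overlap within 1 kb and arms as the unit. With p under 0.0001, tumor kept 18 lower and 0 higher positions (100% lower), peripheral tissue 11 lower and 160 higher (93.6% higher), the table of all groups kept 0 lower and 0 higher, and 0 were shared in either direction. At that threshold 1 autosome was called for peripheral tissue, and the odds ratio of the centromere flanks was 5.38 (Fisher's exact p = 0.102). With flanks of 2 Mb it was 0.772 (Fisher's exact p = 0.754), the other direction and not called, and the odds ratio of the chromosome ends in peripheral tissue was 0.132 for 5 Mb (Fisher's exact p = 0.00995), 0.190 for 10 Mb (p = 0.0259) and 0.438 for 2 Mb (p = 0.411). Fewer positions remain there, 171 of 15905, and the cause was not tested further. With p under 0.00001, tumor and the 3-group table had 0 in either direction, and peripheral tissue 0 lower and 25 higher (100% higher). Merging within 1 kb gave 9407 lower regions in tumor (97.1% lower), 72.1% higher in peripheral tissue and 96.2% lower in the 3-group table. It turned the odds ratio of the gained arms in peripheral tissue from 0.957 to 1.02, neither called, and the cause was not tested. With arms as the unit the odds ratio of the lost arms in peripheral tissue was 1.36 and no longer called (exact permutation test, adjusted p = 0.413). Single arms vary widely and far fewer units are compared, and which of these lost the call was not tested. With autosomes as the unit, median odds ratios were 15.6 for the flanks in peripheral tissue (exact sign test, p = 0.00635, 12 autosomes), 0.453 for the ends in tumor (p = 0.0215, 10 autosomes) and 0.259 in peripheral tissue (p = 1.10e-05). The minimum of 5 expected positions per autosome was set after a run without it, and the 3-group table had too few. Without the centromere flanks, 71.5% of peripheral positions were higher. Among positions under an absolute log2 fold change of 5, 28 were lower and 1283 higher in peripheral tissue (97.9% higher). Counting positions within 1 kb as shared gave 1768 lower ones.

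No paired analysis was possible because no values per sample were at hand. For the same reason other normalizations, filters, count tests, a fit of all 18 samples, leaving out replicates and other splits of the samples were not run. The adjusted p as a threshold was not run because the number of tests is not given in the sources used here. Alternatives on gene lists and genomic context were not run. Depth cannot be judged from these tables.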

Other observations

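Tests on depth, satellite copies, lane and the chromosome 1 cluster were chosen after the results were seen, as were the clusters named here, while the test on copy loss was set before. A stretch of chromosome 1 between 3005141 and 3138008 had mostly lower positions in each table. It held 51 positions lower and 2 higher in tumor, 64 lower and 0 higher in peripheral tissue, and 41 lower and 0 higher in the 3-group table. In the authors' deposited tables their median log2 fold changes were -5.53 in tumor and -5.61 in peripheral tissue. Over all listed positions 97.9% were lower in tumor, 96.8% in the 3-group table and 26.1% in peripheral tissue. Only in peripheral tissue does the share lower in this stretch stand far from that over all positions.

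In a pair of clusters on chromosome 19, more lower positions were listed for peripheral tissue than for tumor, while the whole chromosome had 442 lower in peripheral tissue and 1442 in tumor. Between 36759878 and 36798390 there were 80 positions lower in peripheral tissue and 4 in tumor. Between 37759701 and 37793492 there were 48 and 13. None was higher in either table. Whether tumor and peripheral tissue differ there was not tested, since a position missing from a table has no value.

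Within 1 kb of each other, rather than at identical positions, 1768 of the positions lower in tumor (12.4%) had a neighbour lower in peripheral tissue, against a mean of 45.7 (SD 11.3, highest 76) in 100 shuffles. Of those higher in tumor, 96 (30.8%) had a neighbour higher in peripheral tissue, against a mean of 1.93 (highest 7). Shuffling ignores where CpG sites and reads lie, so both means are too low a measure of chance.

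In tumor 610 positions (4.18%, exact 95% interval 3.86 to 4.52) had p under 0.001, where evenly spread p-values below the table's threshold would give 10%. The share was 8.53% in peripheral tissue and 1.95% in the 3-group table. In peripheral tissue 1.08% were under 0.0001, where an even spread gives 1%, and 25 were under 0.00001 (exact 95% interval 16.2 to 36.9), where it gives 15.9. No position of the other tables was under 0.00001. Neighbouring positions are not independent, so these intervals are too narrow, and an excess under 0.00001 in peripheral tissue cannot be read from them.

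Most listed positions were lower in tumor. Loss of DNA copies as the whole cause is argued against: on all 39 autosomal arms with 20 or more positions most were lower, the least on 12p with 92.3% (84 of 91, exact interval 84.8 to 96.9), though that interval includes the bound of 90% set beforehand. Unequal depth of tumor and normal libraries remains open and could give this direction, because 99.8% of the lower positions lie on the curve of reads in 1 group alone, at low level, and library totals are not in the tables. A difference between tumor and normal tissue also stays open. No test here separates the last 2.

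Higher positions beside the centromeres were listed for peripheral tissue. At 340 bp (give or take 2), the spacing of an alpha satellite dimer, lay 84 pairs of these positions, against a mean of 36.0 and a highest count of 58 in 1000 random placements that kept short clusters together (permutation p = 0.001, the smallest they can give). An earlier, looser placement of single positions was replaced after its outcome was seen. The spacing is what positions in such a repeat would have and says nothing of why the groups differ, since the reference is the same for both. Copies per group were not measured, so collapsed copies stay open. In the tumor table, whose groups share a lane, 0.323% of the higher positions lay in these flanks, but lane and tissue coincide for the peripheral samples and cannot be told apart. A difference of peripheral tissue stays open and untested.

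The cluster on chromosome 1 from 228744549 to 228782124 held 115 positions lower in tumor over 37.6 kb, 0 listed for peripheral tissue and 22 lower in the 3-group table. Copies of a tandem repeat collapsed onto the reference might place positions at 1 spacing, though this alone would not set tumor apart from normal tissue. The most frequent spacing, 1390 bp, had 15 pairs, against a mean of 11.6 and a 95th percentile of 15 in 1000 random placements (permutation p = 0.06), which leaves this open. A difference of tumor tissue was not tested apart from it.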
